A study of Rattus norvegicus with 8 samples.

How the data were processed

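Livers of male Wistar rats with CCl4-induced cirrhosis were profiled on 8 arrays, 4 labelled as given vehicle, which the series description calls untreated, and 4 labelled as given an antiangiogenic treatment. Each array was assigned to its group and replicate number by the sample title. Per the labels' protocols, RNA of frozen liver tissue was isolated with Trizol, cleaned on RNeasy columns, reverse transcribed with an oligo(dT) primer carrying a T7 promoter, and transcribed into biotinylated cRNA, which was hybridized to Affymetrix Rat2302 arrays. Because cRNA made this way starts at the 3′ end of transcripts, the signal of a probe set depends on RNA integrity and on its distance from that end. Per the submitters' processing notes, the arrays were processed with affy and RMA, which corrects background, normalizes probe intensities by quantiles across arrays and summarises the probes of each probe set. Versions and settings of these tools are not given in the sources used here. RMA fits all arrays together and draws small differences at low intensity towards 0, so that fold changes of dim genes tend to be understated.

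The deposited values are on the log2 scale (8 arrays, 31099 probe sets), as the range of the values shows, and were used as deposited. The 57 control probe sets were left out of the tests, which leaves 31042. No array column was left unused. Array values carry no count of molecules, so that the number of arrays (n = 4 per group) and the brightness of a probe set limit the precision. No detection calls were used here. Gene names came from the platform annotation, in which 20826 of the tested probe sets had 1 gene symbol, 436 had several and 9780 had none listed. Of the probe sets with 1 symbol, 20758 had their gene identifier in a RefSeq gene table of the rat assembly GRCr8, and 0 symbols needed updating. Probe sets with several or no symbols were tested but not named. Genome positions are not given, since the sources used here name no genome build.

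All comparisons are treated minus vehicle. The main model was limma (version 3.58.1, R 4.3.3), with lmFit and eBayes on the 8 arrays, no covariates and 6 residual degrees of freedom before moderation, and Benjamini-Hochberg adjustment over the 31042 probe sets. A probe set counted as changed at an adjusted p under 0.05, and a second count required a change of at least 2-fold. Standard errors and 95% intervals come from the moderated variances, and SDs are those of the 4 arrays. For gene lists, each of 14217 genes was represented by the probe set with 1 symbol and the highest mean over the 8 arrays. The 33 lists, with 972 distinct genes, cover angiogenic signalling, endothelium, stellate cells, matrix, leukocytes, mast cells, blood cells, bile ducts, neighbouring tissues, hepatocyte metabolism, stress responses, the cell cycle and the circadian clock. Some genes stand in more than 1 list. Lists were tested with camera (limma) at a preset inter-gene correlation of 0.01 when at least 5 genes were measured, with Benjamini-Hochberg adjustment over the 33 lists. Camera with an estimated correlation, fry and an exact two-sided permutation test of the list means (70 assignments, smallest possible p 0.0286) are given beside it. The preset correlation assumes nearly independent genes, and the correlations estimated here reached 0.798 in the cell cycle list, which makes the preset p-values of such lists small.

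The text names genes by a rule. It takes 12 genes of vessels, fibrosis and leukocytes. It adds, for each direction, the 8 genes with the largest change among those past the threshold without overlap between the groups. Where fewer pass, those with the smallest unadjusted p fill the places, and since no gene passed, all 16 were chosen that way. In each list called by camera it adds up to 3 members past the threshold, or the members with the smallest unadjusted p up to 2. The design, the alternatives, the lists and this rule were fixed before the data were examined, except where the text says that a choice was made after seeing the data.

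RNA quality was measured as the log2 ratio of the 3′ to the 5′ control probe sets of Gapdh and beta-actin, with an exact two-sided permutation test. Hybridization groups were read from the bacterial spike-in controls BioB and BioC, after seeing the data. Alternatives were quantile normalization or median centring of the deposited values, filters at the 40th percentile or at a mean log2 value of 6, eBayes with trend and robust settings, a linear model without moderated variances, array weights, the replicate number as a block, the Gapdh ratio as a covariate, the mean of all probe sets of a gene, and leaving out each array in turn. Leaving out the 2 nearly identical arrays, blocking on the hybridization group and the permutation test of list means were added after seeing the data. Every count was also computed for all 35 splits of the 8 arrays into 2 groups of 4.

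The procedure was tested on simulated data with the real means and spreads. The changed probe sets were drawn from those with a mean log2 value above 6, so that the recovery does not cover dimmer ones. At an adjusted p of 0.05 the procedure recovered 7.46% of 67 probe sets changed 1.5-fold, 52.2% of 67 changed 2-fold and 83.3% of 66 changed 4-fold, with 4 false calls among 99 for the 31042 probe sets of the comparison. For the lists, 3 of 3 shifted by −0.5 were recovered and 2 others were called in error, and in 20 simulations without change, 2 runs called a list. Genes and arrays were simulated independently of each other. These rates therefore do not cover correlated genes or a near-copy of 1 array in each group, as described below. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.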

Results

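Transcript levels were measured on 8 arrays in livers of male Wistar rats with cirrhosis induced by inhaled carbon tetrachloride (CCl4), a hepatotoxin given while the animals drank water with 0.3 g/L phenobarbital, an inducer of hepatic drug metabolism. According to the sample labels, 4 rats received vehicle and 4 received an antiangiogenic treatment, that is, one meant to limit the formation of new blood vessels. The series description calls the control rats untreated, and the sources used here do not settle whether they were given a vehicle. Differences below are therefore against the rats labelled vehicle. The compound and its dose are not given in the sources used here. By the labels each liver was hybridized to 1 Affymetrix Rat2302 array, a high-density array of short oligonucleotide probes, and the deposited values are log2 intensities summarised by robust multi-array average (RMA). Median log2 values lay between 5.163 and 5.299 on the 8 arrays over 31042 probe sets. The number of arrays limits the precision of every value below. The comparison asks how the liver transcriptome of cirrhotic rats differs with antiangiogenic treatment, with inflammatory cells, fibrosis and portal pressure among the stated interests of the study. Values after ± are SDs over 4 arrays per group, differences are treated minus vehicle on the log2 scale, and the probe set of each gene stands in parentheses. Signal was not tested against background, so that levels without a difference are given for genes with a group mean at or below the 25th percentile of an array (3.74 to 3.91).

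No difference in labelling quality was detected between the groups. The log2 ratio of the 3′ to the 5′ Gapdh control probe sets was 0.301 ± 0.113 in vehicle and 0.288 ± 0.114 in treated livers (exact permutation p = 0.914, n = 4 per group, two-sided), and that of beta-actin was 1.83 ± 0.094 and 1.82 ± 0.060 (exact permutation p = 0.857, n = 4 per group; adjusted p = 0.914 for both). The sign of both differences turned when single arrays were left out. The spiked-in bacterial controls divided the arrays into 3 hybridization groups. Vehicle 1 and treated 1 formed the first, with BioC 1.48 and 1.32 above BioB. Vehicle 4 and treated 3 formed the third, with the highest BioB levels, 8.97 and 8.87, and the other 4 arrays formed the second. Each hybridization group therefore held as many vehicle as treated arrays. Spike-in levels were not balanced within them. BioB was 7.39 on vehicle 1 and 7.97 on treated 1 in the first group. In the second it was 7.52 and 7.43 on vehicle 2 and 3, and 8.08 and 7.81 on treated 2 and 4.

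Vehicle 4 and treated 3 were nearly identical. Their values correlated at r = 0.996 across probe sets, which are not independent replicates, and the median absolute deviation of their difference was 0.0943, against 0.269 to 0.627 in the 27 other pairs. None of 9235 probe sets with a mean above 7 differed more than 2-fold between them (0), against 245 to 1627 in the other pairs. Both were kept under their labels, so that a near-copy of 1 array stands in each group and n = 4 per group counts arrays, and the results without both arrays are given beside the counts below.

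**Figure D1:**
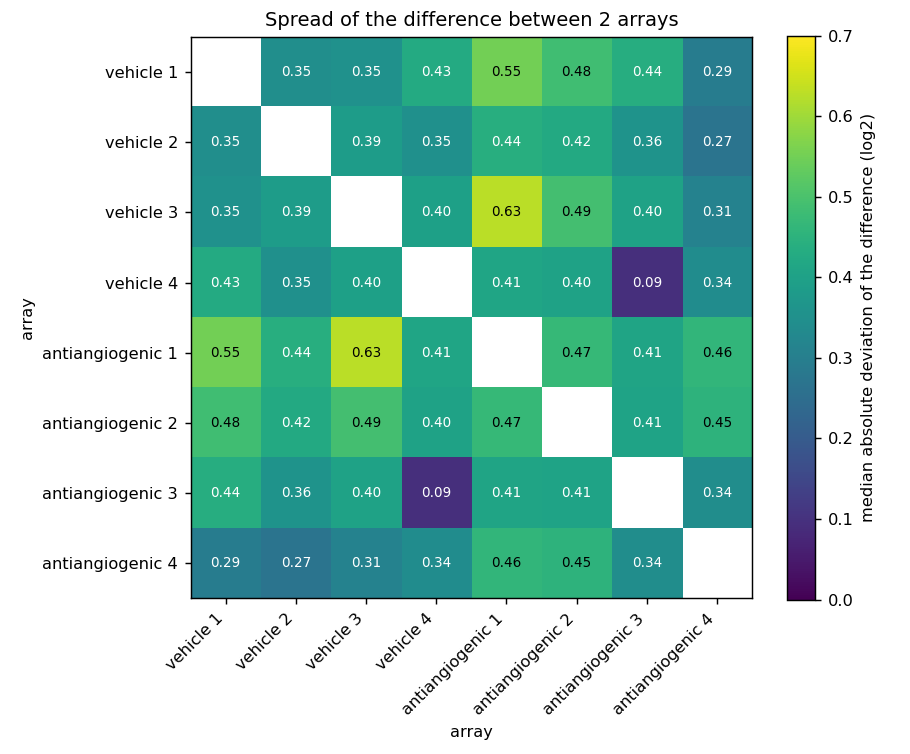
Median absolute deviation of the difference in log2 value between every 2 of the 8 arrays (both axes list the arrays, the colour scale is in log2 units, and the diagonal is left blank). Vehicle 4 and antiangiogenic 3 (treated 3) differed by 0.0943, and the closest of the other pairs by 0.269.

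Gene groups typical of blood vessels, scar matrix, leukocytes, mast cells and dividing cells were lower in treated livers with a preset inter-gene correlation, and drug-metabolizing, bile acid, fatty acid oxidation and oxidative stress genes were higher. None of these calls held with a correlation estimated from the data (0 of 33 lists, smallest adjusted p = 0.190 with an estimated correlation), although 7 lists had an unadjusted p under 0.05 there. Fry called 0 lists (smallest adjusted p = 0.169). An exact permutation test of the list means, chosen after seeing the data, also called 0 (smallest adjusted p = 0.343), but it could hardly call any, since at least 19 of the 33 lists would have to reach its smallest p of 0.0286. Of 33 gene lists fixed beforehand, 20 passed an adjusted p of 0.05 in camera (limma) with the preset inter-gene correlation of 0.01, of which 16 fell and 4 rose. The largest falls were in the cell cycle list, with a median log2 difference of −0.86, in collagens and structural matrix (−0.69) and in vascular endothelial markers (−0.55). The largest rise was in xenobiotic metabolism, with a median of 0.46. The list means of the groups overlapped in every list (0 of 33 without overlap). A near-copy of 1 array in each group makes overlap likely, so the 2.86% expected of independent arrays is no guide.

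No single gene passed the threshold. Across 31042 probe sets, limma with Benjamini-Hochberg adjustment called 0 at an adjusted p of 0.05 (smallest adjusted p = 0.979) and 0 with a change of at least 2-fold. At an unadjusted p of 0.05, 1220 probe sets differed, 586 higher and 634 lower. The 1552.1 expected of independent arrays is not the chance level here, since a near-copy of 1 array stands in each group. The 19 other splits into groups of 4 that part the near-identical arrays had a median of 671. Leaving out 1 array moved the count of 1220 to between 538 (without treated 1) and 2885 (without treated 4). The groups did not overlap at 518 probe sets (1.67%), 338 of them higher and 180 lower in treated livers. The 2.86% expected of independent arrays is no guide here either, for the same reason. Absence of overlap, here and for the genes named below, requires the near-identical vehicle 4 and treated 3 to lie apart. It therefore rests partly on how these near-copies differ. Without vehicle 4 the adjusted count was 11, all lower in treated livers, and without both near-identical arrays it was 3, also lower. Those 3, which were among the 11, were singled out after their values were seen: the mast cell genes Cpa3 (carboxypeptidase A3, adjusted p = 0.0147) and Cma1 (chymase, adjusted p = 0.0388), and the endothelial tight junction gene Cldn5 (−2.26, adjusted p = 0.0388), all by limma on 6 arrays. Over all 8 arrays Cpa3 averaged 6.87 ± 2.03 in vehicle and 3.80 ± 0.15 in treated livers.

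**Figure D2:**
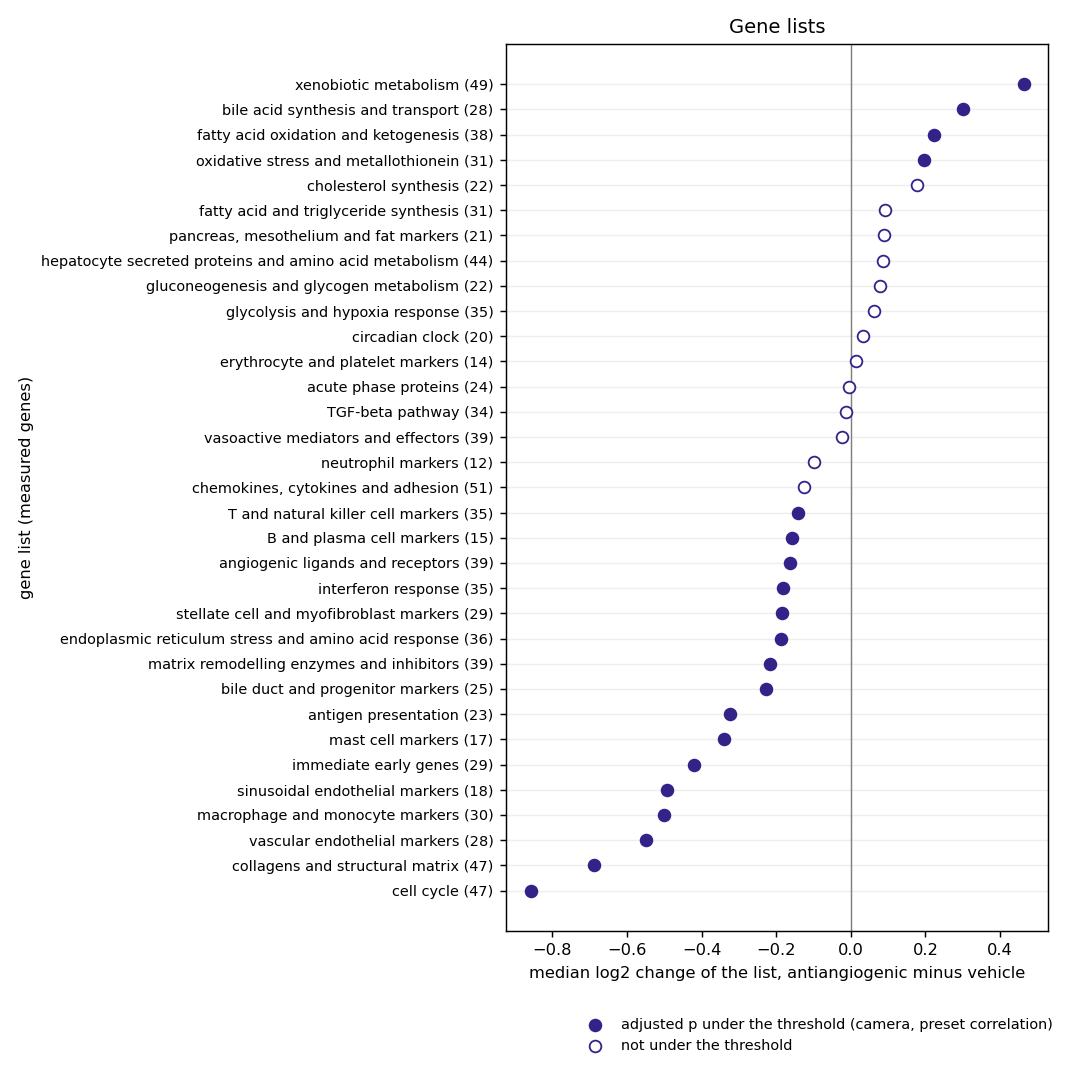
Median log2 difference, treated minus vehicle, of the 33 gene lists (horizontal axis, log2 units), with the number of measured genes of each list in parentheses; filled circles mark the 20 lists called by camera with the preset correlation. Medians ran from −0.86 for the cell cycle list to 0.46 for xenobiotic metabolism, and none of the calls held with an estimated correlation.

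Vascular endothelial markers fell in treated livers, with 25 of 28 measured genes lower and a median difference of −0.55 (camera adjusted p = 3.91e-15; adjusted p = 0.190 with an estimated correlation). Of these genes, 0 passed over all probe sets, and 9 passed when adjusted over the list alone. Nos3 (1371166_at), the endothelial nitric oxide synthase, averaged 5.44 ± 0.20 in vehicle and 4.76 ± 0.23 in treated livers, a level 1.61-fold lower with no overlap between the groups (difference −0.68, SE 0.15, limma adjusted p = 0.979). Aqp1 (1387651_at), a water channel of endothelium and bile ducts, averaged 8.15 ± 0.50 and 7.09 ± 0.46, and Pecam1 (1371545_at), an endothelial adhesion molecule, 6.51 ± 0.31 and 6.15 ± 0.25 (difference −0.36, and −0.21 without vehicle 1). Sinusoidal endothelial markers fell as well, with 15 of 18 lower and a median of −0.49 (camera adjusted p = 2.19e-06; adjusted p = 0.210 with an estimated correlation). Fcgr2b (1371079_at), the inhibitory Fc receptor, averaged 9.56 ± 0.24 and 8.74 ± 0.46, and Bmp2 (1398270_at), a ligand that controls hepatic iron balance, 7.31 ± 0.35 and 6.54 ± 0.39.

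Angiogenic ligands and receptors fell by less, with 28 of 39 lower and a median of −0.16 (camera adjusted p = 0.00568; adjusted p = 0.357 with an estimated correlation). Kdr (1367948_a_at), the main signalling receptor for vascular endothelial growth factor, averaged 7.61 ± 0.90 in vehicle and 6.82 ± 0.65 in treated livers (difference −0.78, 95% interval −1.83 to 0.27), while its second probe set went the other way (0.19). The Kdr difference was −0.47 without vehicle 2, −1.20 without vehicle 4 and −0.30 with the mean of its probe sets. Flt1 (1369087_at), a second receptor of this ligand, differed by −0.24 (−0.50 to 0.01), and by −0.42 with the mean of its probe sets. Vegfa (1373807_at), the ligand itself, averaged 9.16 ± 0.28 and 9.55 ± 0.24 (difference 0.40, 95% interval 0.00 to 0.79, limma adjusted p = 0.979), and differed by 0.26 without vehicle 3. Pdgfc (1387616_at), a platelet-derived growth factor, differed by 0.44, and Angpt2 (1374207_at), a ligand of the Tie2 receptor, averaged 4.98 ± 1.04 and 3.91 ± 0.30. Without vehicle 2 the list was no longer called (median −0.12, adjusted p = 0.103). Its median was −0.38 over probe sets with a mean above 6 and −0.09 with the mean of all probe sets of a gene.

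Within the hybridization groups, the 3 vessel lists were lower in treated livers in the first and second groups and near 0 in the third. Vascular endothelial markers had a median difference of −0.85 in the first, −0.62 in the second and −0.03 in the third, which holds the near-identical arrays. Those of sinusoidal endothelial markers were −0.65, −0.50 and 0.02, and those of angiogenic ligands and receptors −0.27, −0.19 and 0.04. In the third group, every one of the 33 lists had a median between −0.05 and 0.09, so its values are not repeated for the lists below. With the hybridization group as a block, chosen after seeing the data, 20 lists and 0 probe sets were called. On vehicle 4 the mean of the vascular endothelial list was 6.52, against 7.18, 7.05 and 7.12 on vehicle 1 to 3 and 6.32 to 6.58 on the treated arrays.

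**Figure D3:**
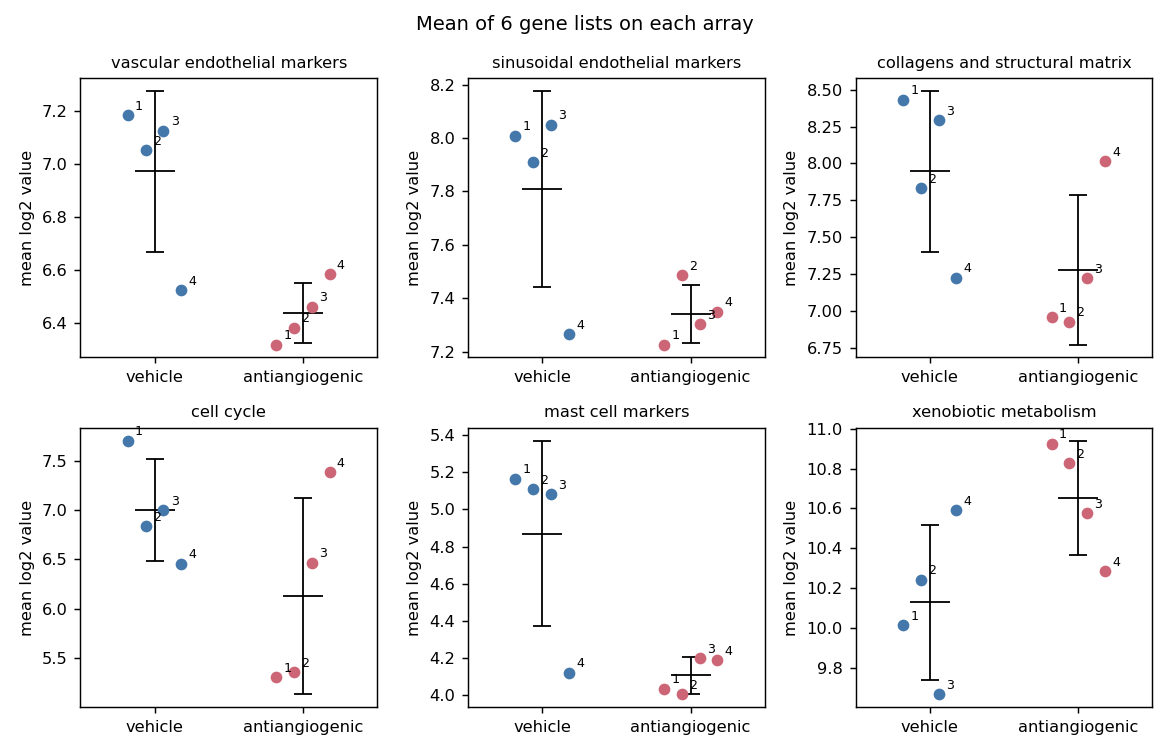
Mean log2 value (vertical axis, a different range in each panel, not starting at 0) of 6 gene lists on each array, with points numbered by replicate and bars giving the group mean ± SD of 4 arrays. For mast cell markers, vehicle 1 to 3 lie at 5.08 to 5.17, vehicle 4 at 4.12 and the treated arrays at 4.01 to 4.20.

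Collagens and structural matrix fell, with 45 of 47 genes lower and a median of −0.69 (camera adjusted p = 3.44e-16; adjusted p = 0.296 with an estimated correlation). The groups overlapped, with list means of 8.43, 7.83, 8.29 and 7.22 on vehicle 1 to 4 and 6.96, 6.93, 7.22 and 8.01 on treated 1 to 4. Col1a1 (1388116_at), the main fibrillar collagen chain of scar tissue, averaged 9.58 ± 1.08 in vehicle and 8.30 ± 0.90 in treated livers, 2.43-fold lower with a 95% interval of the difference from −2.60 to 0.04. Col5a3 (1368347_at) averaged 5.02 ± 0.16 and 4.55 ± 0.10 without overlap, and Fbln2 (1389533_at), an extracellular matrix glycoprotein, 5.78 ± 0.23 and 5.35 ± 0.15. For Col5a3 the near-identical vehicle 4 and treated 3 stood at 5.23 and 4.67, further apart than the group means. Matrix remodelling enzymes and inhibitors fell, with 31 of 39 lower and a median of −0.22 (camera adjusted p = 0.000421; adjusted p = 0.357 with an estimated correlation). Among these, the metalloproteinase inhibitors Timp1 (1367712_at) and Timp3 (1389836_a_at) differed by −0.73 (−2.10 to 0.64) and −0.75 (−1.27 to −0.22), and Loxl1 (1388902_at), which crosslinks elastin, by −1.23 (−2.37 to −0.08). The Timp1 difference was −0.20 without treated 1, −0.40 without vehicle 3 and −1.10 without treated 4, and that of Timp3 −0.44 with the mean of its probe sets. The median of this list was −0.12 without vehicle 3, −0.34 without vehicle 4, −0.13 without treated 1 and −0.35 without both near-identical arrays. It was −0.37 under either filter on dim probe sets and −0.14 with the mean of all probe sets of a gene.

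Stellate cell and myofibroblast markers fell, with 20 of 29 lower and a median of −0.19 (camera adjusted p = 0.000536; adjusted p = 0.190 with an estimated correlation). Acta2 (1370857_at), the smooth muscle actin of activated stellate cells, averaged 6.81 ± 0.40 in vehicle and 6.15 ± 0.27 in treated livers, 1.59-fold lower (difference −0.67, 95% interval −1.15 to −0.18, limma adjusted p = 0.979). Meox1 (1393974_at), a homeobox transcription factor, averaged 3.63 ± 0.22 and 3.14 ± 0.03 without overlap, and Myl9 (1388298_at), a regulatory myosin light chain of smooth muscle, 8.52 ± 0.37 and 7.93 ± 0.06. Pdgfrb (1370642_s_at), a growth factor receptor of stellate cells and pericytes, differed by −0.92 (−2.10 to 0.26), and by −0.44 with the mean of its probe sets. The TGF-beta pathway list was not called (18 of 34 lower, median −0.01, camera adjusted p = 0.338), and its median is smaller than the 0.0535 that median centring of the arrays adds to every difference. Tgfb1 (1370082_at), its main profibrotic ligand, averaged 6.26 ± 0.30 and 5.59 ± 0.44 (difference −0.67, 95% interval −1.20 to −0.15). In the first hybridization group the medians were −1.55 for collagens, −0.60 for remodelling enzymes and −0.32 for stellate markers, and in the second −0.68, −0.16 and −0.17. The stellate median was −0.35 over probe sets with a mean above 6 and −0.12 with the mean of all probe sets of a gene.

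**Figure D4:**
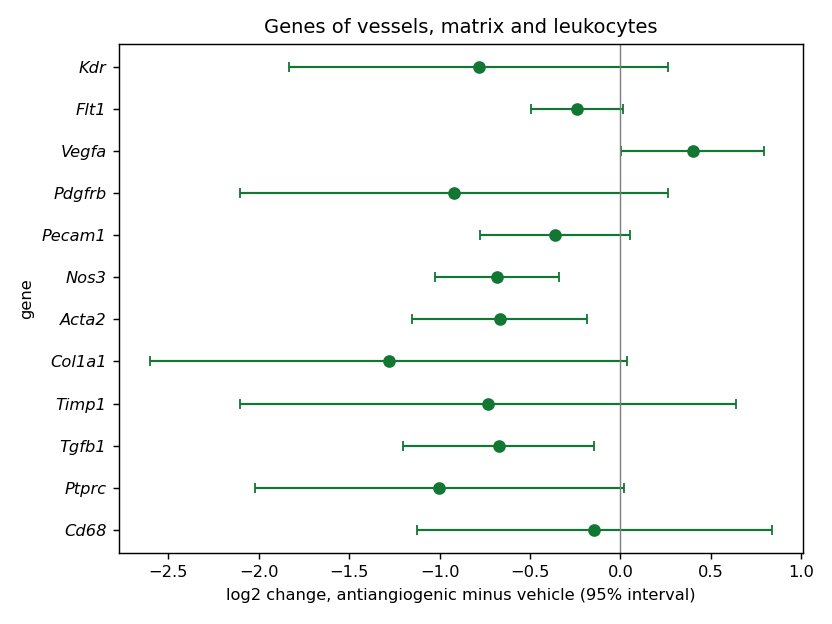
Log2 difference, treated minus vehicle (horizontal axis, log2 units), of the 12 genes of vessels, matrix and leukocytes named beforehand; points are limma estimates from 4 arrays per group and bars their 95% intervals. Estimates ran from −1.28 for Col1a1 to 0.40 for Vegfa, and none passed the adjusted threshold.

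In treated livers 5 leukocyte and immune response lists fell. Macrophage and monocyte markers were lower at 25 of 30 genes with a median of −0.50 (camera adjusted p = 3.99e-05; adjusted p = 0.400 with an estimated correlation), and treated 2 and 4, with list means of 8.498 and 9.04, lay within the vehicle range of 8.41 to 9.19. Antigen presentation genes were lower at 20 of 23 with a median of −0.32 (camera adjusted p = 5.77e-08; adjusted p = 0.210 with an estimated correlation). T and natural killer cell markers were lower at 28 of 35 with a median of −0.14 (camera adjusted p = 0.000224; adjusted p = 0.249 with an estimated correlation). B and plasma cell markers were lower at 11 of 15 with a median of −0.16 (camera adjusted p = 0.00203; adjusted p = 0.190 with an estimated correlation), and 2 of them, Fcmr and Fcrla, passed when adjusted over the list alone. Interferon response genes were lower at 25 of 35 with a median of −0.18 (camera adjusted p = 0.000287; adjusted p = 0.210 with an estimated correlation).

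Ptprc (1390798_at), the pan-leukocyte antigen CD45, averaged 8.31 ± 0.79 in vehicle and 7.31 ± 0.73 in treated livers, a difference of −1.001 (−2.02 to 0.02). The macrophage gene Cd68 (1375010_at) averaged 9.74 ± 0.46 and 9.60 ± 0.93, and its difference of −0.14 turned to 0.195 without treated 1. It was −0.06, −0.36 and −0.01 without vehicle 1, 2 and 3, and −0.04 and −0.55 without treated 2 and 4. Lyz2 (1370154_at), lysozyme, differed by −0.87 (−1.81 to 0.07), and Fcgr1a (1393038_at), the high-affinity IgG receptor, by −0.62 (−1.30 to 0.05), and by −0.35 without treated 1. The class II histocompatibility genes RT1-Ba (1370822_at) and RT1-Da (1370883_at) averaged 9.46 ± 1.93 against 7.05 ± 0.71 and 11.39 ± 2.01 against 8.98 ± 0.96, with vehicle 4 at 6.7 and 8.4. With the mean of its probe sets RT1-Ba differed by −0.97. The lymphocyte genes Cd3e (1379791_at), a T cell receptor subunit, and Cd4 (1369483_at), a co-receptor, differed by −0.69 (−0.40 with the mean of its probe sets) and −0.77, and Fcmr (1382184_at), the IgM receptor, and Fcrla (1392886_a_at) by −1.04 and −0.62. The antiviral gene Mx1 (1371015_at) and the interferon regulator Irf7 (1383564_at) differed by −0.98 and −0.89. Macrophage markers had a median of −0.18 without treated 1 and −0.84 without treated 4, B cell markers −0.30 without vehicle 3, and interferon genes −0.08 without treated 2 and −0.28 without treated 3. The interferon median was −0.09 over probe sets with a mean above 6, and the shift of all genes by median centring left −0.09 for T cell and −0.10 for B cell markers. Over probe sets above the 40th percentile the B cell median was −0.62. In the first and second hybridization groups the medians were −1.56 and −0.18 for macrophage markers, −0.73 and −0.43 for antigen presentation, −0.20 and −0.22 for T cells, −0.14 and −0.24 for B cells, and −0.19 and −0.23 for interferon genes.

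Mast cell markers fell, with 14 of 17 lower, a median of −0.34 and a mean of −0.76 (camera adjusted p = 2.19e-06; adjusted p = 0.210 with an estimated correlation), and 5 passed when adjusted over the list alone. Mcpt10 (1371164_at), a mast cell protease, averaged 6.30 ± 1.08 in vehicle and 3.86 ± 0.66 in treated livers without overlap (limma adjusted p = 0.979). Its lowest vehicle and highest treated values were those of the near-identical vehicle 4 (4.76) and treated 3 (4.67). Cma1 (1387173_at), mast cell chymase, averaged 4.92 ± 0.82 and 3.57 ± 0.25. The median of the list was −0.77 without vehicle 4, −0.59 without treated 4, −0.64 with array weights and −0.74 over probe sets above the 40th percentile, and it was −0.70 in the first and −0.60 in the second hybridization group. Neutrophil markers were not called (8 of 12 lower, median −0.10, camera adjusted p = 0.220), nor were chemokines, cytokines and adhesion molecules (34 of 51 lower, median −0.13, camera adjusted p = 0.0638). The chemokine list was called lower without vehicle 3 (adjusted p = 0.0310), vehicle 4 (0.00952), treated 2 (1.05e-05) or both near-identical arrays (0.0217). It was also called with median centring (0.0152), over probe sets with a mean above 6 (0.0425), with array weights (0.0357) and with the mean of all probe sets of a gene (0.0355), and its median was 0.02 without treated 1.

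Xenobiotic metabolism genes rose, with 42 of 49 higher and a median of 0.46 (camera adjusted p = 4.11e-10; adjusted p = 0.220 with an estimated correlation). Vehicle 4, with a list mean of 10.59, lay above treated 3 and 4 (10.575 and 10.29). Cyp2j4 (1387296_at), a cytochrome P450, averaged 8.83 ± 0.44 in vehicle and 9.62 ± 0.23 in treated livers, 1.73-fold higher (limma adjusted p = 0.979), and Fmo1 (1387053_at), a flavin monooxygenase, 8.13 ± 1.10 and 9.94 ± 0.77, 3.53-fold higher. Bile acid synthesis and transport genes rose, with 21 of 28 higher and a median of 0.30 (camera adjusted p = 0.000154; adjusted p = 0.357 with an estimated correlation). Their members Cyp27a1 (1387914_at), which hydroxylates the sterol side chain, and Scp2 (1370296_at), a sterol carrier and peroxisomal thiolase, differed by 0.40 (0.04 to 0.75) and 0.29 (0.03 to 0.56). Fatty acid oxidation and ketogenesis genes rose, with 32 of 38 higher and a median of 0.22 (camera adjusted p = 6.53e-05; adjusted p = 0.349 with an estimated correlation). The acyl-CoA dehydrogenases Acadm (1367702_at) and Acadvl (1367897_at) differed by 0.30 and 0.31. Oxidative stress and metallothionein genes rose, with 23 of 31 higher and a median of 0.20 (camera adjusted p = 0.00302; adjusted p = 0.357 with an estimated correlation). Prdx6 (1367969_at), a peroxiredoxin, and Nqo1 (1387599_a_at), a quinone reductase, differed by 0.35 (0.06 to 0.65) and 0.80 (0.07 to 1.53), the latter 0.53 without vehicle 1.

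Without treated 2 the oxidative stress list was no longer called (adjusted p = 0.224). The bile acid median was 0.18 without treated 1 and 0.47 without treated 4, and the fatty acid oxidation median 0.15 without treated 4. In the first and second hybridization groups the medians were 0.91 and 0.49 for xenobiotic metabolism, 0.89 and 0.26 for bile acids, 0.12 and 0.39 for fatty acid oxidation, and 0.21 and 0.30 for oxidative stress. Other metabolic lists were not called: hepatocyte secreted proteins and amino acid metabolism (26 of 44 higher, median 0.09, camera adjusted p = 0.161), cholesterol synthesis (18 of 22, 0.18, adjusted p = 0.0505), fatty acid and triglyceride synthesis (17 of 31, 0.09, adjusted p = 0.323), and glycolysis and hypoxia response (23 of 35, 0.06, adjusted p = 0.229). Cholesterol synthesis was called higher without vehicle 2 (adjusted p = 0.000861), vehicle 4 (0.0481), treated 2 (0.00177) or treated 4 (0.00752), over probe sets above the 40th percentile (0.0446), with trend and robust settings (0.0475) and with the Gapdh covariate (0.0311), and its median was −0.07 without treated 1. Secreted proteins were called higher without vehicle 1 (0.0466) or vehicle 2 (0.0188), and glycolysis without vehicle 1 (0.0407) or treated 1 (0.00341).

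All 47 measured cell cycle genes were lower in the treated group means, and the list fell with a median of −0.86 (camera adjusted p = 3.88e-15; adjusted p = 0.357 with an estimated correlation). Ccnd1 (1383075_at), cyclin D1, averaged 9.97 ± 0.34 in vehicle and 8.74 ± 1.18 in treated livers, and Ccnb2 (1389566_at), a mitotic cyclin, 7.35 ± 0.83 and 5.84 ± 1.51. The Ccnd1 difference of −1.23 was −0.82 without treated 1. Treated arrays were far apart, with list means of 5.302 and 5.36 on treated 1 and 2, 6.46 on treated 3 and 7.38 on treated 4, against 6.46 to 7.70 on the vehicle arrays. The median was −0.56 without vehicle 1, and it was −2.45 in the first and −0.48 in the second hybridization group. Immediate early genes fell, with 22 of 29 lower and a median of −0.42 (camera adjusted p = 0.000421; adjusted p = 0.486 with an estimated correlation). The orphan nuclear receptors Nr4a2 (1369007_at) and Nr4a3 (1369067_at) differed by −1.28 (−2.08 to −0.49) and −1.88 (−3.32 to −0.45), the latter −0.87 with the mean of its probe sets. This call ended without treated 1 (median −0.05, adjusted p = 0.458), and the median was −0.22 without vehicle 2, −0.77 without treated 2, −0.65 without treated 3 and −0.67 without both near-identical arrays. It was −1.50 in the first and −0.18 in the second hybridization group.

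Genes of endoplasmic reticulum stress and the amino acid response fell with 26 of 36 lower and a median of −0.19 (camera adjusted p = 0.0304; adjusted p = 0.664 with an estimated correlation). Chac1 (1389573_at), which degrades glutathione, averaged 10.43 ± 1.01 and 8.13 ± 1.72, and Vldlr (1389611_at), a lipoprotein receptor, 7.88 ± 0.56 and 6.97 ± 0.73. Without treated 1 their differences of −2.29 and −0.90 were −1.47 and −0.55. The call ended without vehicle 3 (median 0.01), treated 1 (0.03), vehicle 4 (−0.12) or treated 4 (−0.15) and with array weights, and the median was −0.32 without vehicle 1 and −0.30 without treated 3. Bile duct and progenitor markers fell at the edge of the threshold, with 18 of 25 lower and a median of −0.23 (camera adjusted p = 0.0495; adjusted p = 0.574 with an estimated correlation). Ggt1 (1368374_a_at), gamma-glutamyltransferase, averaged 6.49 ± 0.62 and 5.72 ± 0.33, and Prom1 (1368008_at), a progenitor surface marker, 6.87 ± 0.91 and 5.87 ± 0.72. This call ended without vehicle 1 (adjusted p = 0.299), vehicle 2 (0.141), treated 1 (0.0670), treated 2 (0.370, median −0.09) or treated 3 (0.152), and with quantile normalization or the Gapdh covariate. The median was −0.34 under either filter on dim probe sets. In the first and second hybridization groups the medians were −0.29 and −0.25 for the stress genes and −0.72 and −0.03 for bile duct markers.

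The other lists were not called. Vasoactive mediators and effectors had 23 of 39 genes lower and a median of −0.02 (camera adjusted p = 0.231). Pancreas, mesothelium and fat markers had 15 of 21 higher (median 0.09, camera adjusted p = 0.115) and were called higher without treated 1 (adjusted p = 0.0124). Median and mean differed in sign in 4 lists. They were 0.08 and −0.02 for gluconeogenesis and glycogen metabolism (camera adjusted p = 0.559, direction of the test up), and −0.01 and 0.04 for acute phase proteins (adjusted p = 0.657, up). For the circadian clock they were 0.03 and −0.04 (adjusted p = 0.647, down), and for erythrocyte and platelet markers 0.01 and −0.13 (adjusted p = 0.657, down). In the last list 1 gene passed when adjusted over the list alone, the beta-globin gene Hbb (10.75 ± 0.91 and 8.94 ± 0.59), which is singled out after its values were seen.

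The genes with the smallest unadjusted p, none of them past the adjusted threshold, included 8 in each direction, with unadjusted limma p-values from 0.000958 to 0.00602. Of the 8 on the higher side, Tbx3 (1393160_at), a T-box transcription factor, had the largest difference, with 4.82 ± 0.72 in vehicle and 6.45 ± 0.80 in treated livers (3.10-fold, limma adjusted p = 0.979), and its 4 probe sets shared the direction, with a difference of 0.98 for their mean. Pdzph1 (1374375_at) averaged 5.08 ± 0.41 and 6.19 ± 0.60, 2.15-fold higher. C19h16orf74 (1372598_at) differed by 0.81, Glt1d1 (1376295_at) by 0.57, the chemokine gene Ccl27 (1376850_a_at) by 0.51 and Ybey (1378563_at) by 0.39, beside Cyp2j4. Trhde (1382204_at), whose product degrades thyrotropin-releasing hormone, averaged 3.30 ± 0.13 and 3.74 ± 0.10. On the lower side, Napsa (1368521_at), the aspartic protease napsin A, averaged 6.87 ± 0.45 and 5.77 ± 0.25, 2.14-fold lower without overlap (limma adjusted p = 0.979). Pde10a (1368438_at), a cyclic nucleotide phosphodiesterase, differed by −1.31, Spn (1370987_at), the leukocyte sialoglycoprotein CD43, by −0.93, Gnb4 (1371071_at), a G protein subunit, by −0.85, and P2ry6 (1368754_at), a nucleotide receptor, by −0.78, beside Nos3, Mcpt10 and Fcmr.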

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

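The tests of the near-identical arrays and of the mast cell list in this part were all chosen after the result was seen. A sample was singled out where its gap to the nearest other array of its group, divided by the range of the group, exceeded Dixon's 95% limit. Of 98 genes and lists examined per group, 9 in vehicle and 4 in treated livers did so, and vehicle 4 was the outlying array in 6 of the 9. Chance would give about 5 in each group for independent items. The items are not independent, since lists hold some of the genes and most genes were named for a small p in these data. The 5 is therefore no guide.

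Vehicle 4 stood apart from vehicle 1 to 3 in the mast cell list (ratio 0.921), Cma1 (0.875), RT1-Da (0.866) and Spn (0.844), where it was lower, and in Cyp2j4 (0.905) and Fmo1 (0.843), where it was higher. In each of these it lay on the side of the treated arrays. Vehicle 3 stood apart in Vegfa (0.902, lower), the interferon response list (0.935, higher) and the gluconeogenesis and glycogen list (0.839, lower). Among treated livers, treated 3 stood apart in Glt1d1 (0.831, lower), treated 1 in Fcgr1a (0.837, lower), and treated 4 in the bile duct list (0.847, higher) and the fatty acid oxidation list (0.844, higher).

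For the near identity of vehicle 4 and treated 3, at the 500 probe sets that varied most among the other 6 arrays, the median absolute deviation of their difference was 0.106, against 0.823 to 2.23 in the other pairs. Vehicle 1 and treated 1, which also share a hybridization group, lay at 1.75, above the median pair (1.30). Every other pair holds at least 1 of the 6 arrays used for this choice of probe sets, which raises its values. Over the 9235 probe sets with a mean above 7, chosen without regard to spread, vehicle 1 and treated 1 lay at 0.551, against 0.0943. A shared hybridization alone therefore does not account for the near identity. The deviation at the 500 variable probe sets was 1.08 times that at stable ones. It was 4.08 to 10.1 times in the other pairs, whose ratios the choice of probe sets also raises. A ratio near 1 is what the same RNA on both arrays would give. If so, the arrays hold fewer livers than their number and 1 of the 2 labels may be wrong. Its side stays open and neither array was moved or renamed: the mast cell list means of the pair (4.12 and 4.20) lay far below vehicle 1 to 3 (5.08 to 5.17) and close to the other treated arrays (4.01 to 4.19), as did those of the vascular, sinusoidal and antigen presentation lists, while for the interferon list the pair (7.72 and 7.74) lay within vehicle 1 to 3 (7.70 to 8.02) and above the other treated arrays (7.27 to 7.54).

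Mast cell markers were lower in treated livers, and the list separates vehicle 1 to 3 from the other 5 arrays. Inside the second hybridization group, with 2 arrays per group, the list mean was lower by 0.998 (−0.998 treated minus vehicle). A difference between the hybridization groups alone therefore does not account for the lower list. A hybridization source stays open, since the spike-in BioB was 7.39 to 7.52 on vehicle 1 to 3 and 7.81 to 8.97 on the other 5 arrays. A smaller share of all non-hepatocyte cells could not be excluded: after subtracting the mean of 6 other non-hepatocyte lists the difference was −0.401 (SD 0.282 in vehicle and 0.115 in treated livers, exact permutation p = 0.0857, n = 4 per group, two-sided). Fewer mast cells with treatment, or lower transcript levels in them, stay open as biological hypotheses, as does the label of vehicle 4, whose list mean of 4.12 lies among the treated arrays.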

How the results depend on the processing

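Leaving out both near-identical arrays, the hybridization block and the permutation test of list means were chosen after seeing the data, and the other settings before. Across the settings, 1227 of 1231 comparisons of named genes with their main value kept direction and side of the threshold. None of these genes passed in the main model and most were named for a small p in these data. The count was therefore nearly fixed in advance and says little about stability. Spn and Cma1 passed without vehicle 4 and Cma1 without both near-identical arrays. Of the comparisons of lists, 610 stayed as they were, 74 lost the call (most of them under the 3 other list tests), 20 gained one and 17 changed sign.

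No probe set was called in the main model (0) or in any setting that kept all 8 arrays. Leaving out each array in turn gave 0 to 11 probe sets, all lower and all at least 2-fold (0 to 11), where the 11 came without vehicle 4. Leaving out both near-identical arrays gave 3, again 3 lower and 3 at least 2-fold, and the cause was not tested beyond the similarity of the arrays. At an unadjusted p of 0.05 the count of 1220 became 650 without vehicle 1, 626 without vehicle 3, 2466 without vehicle 4, 538 without treated 1, 2885 without treated 4, 2025 without both near-identical arrays, 2047 with array weights, and 792 and 481 under the filters, which test fewer probe sets. The replicate block called 0 probe sets, with 785 at an unadjusted p of 0.05, and 19 lists, losing the bile duct call and no other. Pairing of the samples by replicate number was not seen. Deviations of same-numbered arrays correlated at −0.114, 0.0410, −0.124 and −0.620, and only treated 2 correlated best with the vehicle array of its own number. A shared day or litter cannot be excluded this way, since the arrays are few and the near-identical arrays carry different numbers. Arrays numbered 1 shared a hybridization group, as did those numbered 2, while those numbered 3 and 4 did not.

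The number of lists called was 18 to 21 in all settings of camera with the preset correlation, with 4 to 6 higher. It was 0 with an estimated correlation and 0 by fry, with 0 higher and 0 lower in each. It was also 0 (0 higher, 0 lower) by exact permutation of list means, which says little, since at least 19 lists would have to reach its smallest p of 0.0286 for any to pass. The estimated correlation replaces the preset 0.01 by larger correlations in most lists, and the other 2 test each list on its own rather than against other genes. Median centring adds 0.0535 to every difference, and this shift alone turned the medians of TGF-beta pathway (0.0399), acute phase proteins (0.0474) and vasoactive mediators (0.0298), none of them called.

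Leaving out each array in turn, the sign changed for Cd68 (−0.548 to 0.195) and for the medians of TGF-beta pathway (−0.108 to 0.00626), neutrophil markers (−0.130 to 0.0251), chemokines (−0.281 to 0.0206), triglyceride synthesis (−0.0859 to 0.192), cholesterol synthesis (−0.0718 to 0.367), acute phase proteins (−0.0528 to 0.0255), vasoactive mediators (−0.0851 to 0.000200), endoplasmic reticulum stress (−0.324 to 0.0317), circadian clock (−0.102 to 0.114) and erythrocyte markers (−0.0109 to 0.0637). The same held for the group difference in the Gapdh ratio (−0.0513 to 0.0389) and the beta-actin ratio (−0.0572 to 0.0134). These settings hold fewer samples, and what turned the signs was not tested.

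The model without moderated variances gives no list test, and the mean of probe sets per gene no count of probe sets. Over probe sets with a mean above 6, mast cell, B cell, T cell, neutrophil and erythrocyte lists kept fewer than 5 genes each and were not tested. Signal was not compared with background, which limits the values of dim genes. Over probe sets above the 40th percentile the medians were −0.742 for mast cells and −0.624 for B cells, but a filter on mean brightness keeps genes through their brighter group, so that these medians do not show an effect of low signal.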

Other observations

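The tests of exchanged labels and of the hybridization groups in this part were chosen after the result was seen. The counts over splits were planned, and the zonation lists were added after Tbx3 was seen, with their test written down before it was run.

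Zonation of the liver lobule was examined because Tbx3, a transcription factor found in hepatocytes around the central vein, had the largest difference among the 8 genes with the smallest unadjusted p that were higher in treated livers. Of 13 pericentral hepatocyte genes other than Tbx3, 10 were higher in treated livers, with a median of 0.130 and a mean of 0.267 (standard error of the mean over genes 0.141; camera adjusted p = 0.0394; adjusted p = 0.176 with an estimated correlation; exact permutation p = 0.171, two-sided). Of 13 periportal genes, 10 were lower, with a median of −0.121 and a mean of −0.295 (standard error of the mean over genes 0.122; camera adjusted p = 0.0311; adjusted p = 0.176 with an estimated correlation; exact permutation p = 0.171). These p-values were adjusted over the pericentral and periportal lists alone, not together with the lists fixed beforehand. That adjustment leaves the larger camera value, 0.0394, at its unadjusted size. Neither camera value is therefore comparable with the adjusted p-values of the other lists. A gain of pericentral over periportal expression is a hypothesis that these arrays leave open, and neither list passed when the correlation was estimated. Single members were far apart, from Glul (−0.45) to Slc13a3 (1.46) among pericentral and from Igfbp1 (−1.31) to Pigr (0.19) among periportal genes.

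Without vehicle 4, 11 probe sets passed the threshold, singled out here after their values were seen. Beside Cpa3, Cma1 and Cldn5 they were the mast cell protease Mcpt1 (−3.74), the class II transactivator Ciita (−2.45), which drives expression of class II histocompatibility genes, Spn (−1.14), Fcrl2 (−2.93), the dendritic cell receptor Clec9a (4.30 in vehicle and 3.23 in treated livers over all 8 arrays), Lypd8l1 (5.22 and 3.83) and 2 probe sets without a listed gene.

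Chance was weighed by counting all 35 splits of the 8 arrays into 2 groups of 4. For lists, 3 of 35 splits, the real one included, gave at least the real 20, and the highest other gave 23. Chance therefore cannot be excluded for the number of lists. The split with 23 lists exchanges only the near-identical vehicle 4 and treated 3. Splits with vehicle 1 to 3 on 1 side gave 19 to 23 lists, whichever array joined them, and all other splits 2 to 15. The number of lists thus does not hinge on which array is labelled vehicle beside vehicle 1 to 3. At an unadjusted p of 0.05, 15 of 35 splits, the real one included, gave at least the real 1220 probe sets, and the highest other gave 7057. For probe sets past the adjusted threshold the real count was 0, which 35 of 35 splits reach whatever the values are, so that counting splits decides nothing there, and the highest other split gave 1473. The same holds for those at least 2-fold (35 of 35, real count 0, highest other 687). The 19 other splits that part the near-identical arrays had a median of 671 probe sets at an unadjusted p of 0.05 and 0 with adjusted calls, and the 15 that keep them together a median of 1700 and 5 with adjusted calls.

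The split with 1473 probe sets set vehicle 1 to 3 and treated 4 against vehicle 4 and treated 1 to 3. It may reflect a structure of the samples other than the labels. However, it keeps the near-identical arrays together, as did all 5 splits with adjusted calls. It parts 2 of the hybridization groups, but the second only by treated 2. BioB was lower on vehicle 1 to 3 and treated 4 (7.39 to 7.81) than on the others (7.97 to 8.97). Hybridization therefore cannot be excluded as its source. Exchanged labels of vehicle 4 and treated 4 could not be told apart from other sources: the mast cell list averaged 4.19 on treated 4 and 4.12 on vehicle 4, against 5.12 (SD 0.042) on vehicle 1 to 3 and 4.08 (SD 0.105) on treated 1 to 3. Sinusoidal and vascular endothelial lists did not decide it either. Treated 4 (7.35 and 6.58) lay near vehicle 4 (7.26 and 6.52), both below vehicle 1 to 3, so an exchange would change little there. In other lists treated 4 lay in the range of vehicle 1 to 3 and above vehicle 4, as an exchange would give: collagens (8.01 against 7.22), cell cycle (7.38 against 6.46) and macrophage markers (9.04 against 8.41). Either labelling leaves 1 array with low mast cell genes among the vehicle livers. A treated liver with a weak response and a vehicle liver with little inflammation stay open as well, and were not tested.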
